A study of Mus musculus with 9 samples.

How the data were processed

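Bulk RNA sequencing of CD4+ T cells from a Foxp3-eGFP reporter strain was re-analysed: 9 libraries in 3 groups of 3, namely day 0 eGFP-negative cells, TGFβ-iTreg cells and mTO-iTreg cells. Per the submitters' processing notes, the libraries were made by a modified CEL-Seq method, reads were aligned with BWA to mm10, and counts were normalized with DESeq2; versions and the handling of strand are not given in the sources used here. The deposited table holds normalized counts, that is, counts divided by a size factor per library, with decimal commas and 1 row per gene. Dividing each library by the value of a single count, estimated from its smallest values, gave whole numbers for 100% of values within 0.1, and the sums of these are the depths given with the results. A single count is worth 0.494 to 2.69 normalized counts, which sets the precision for rarely read genes.

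Of 14912 rows, 296 were 0 in every library. The 10983 rows with a value of at least 5 in at least 3 of the 9 libraries were tested. A linear model with 3 group means was fitted to log2 of the normalized values plus 1 with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a mean-variance trend, 6 residual degrees of freedom), a test fixed before the table was opened, because its name gives normalized data. The 3 contrasts were TGFβ-iTreg against day 0, mTO-iTreg against day 0, and mTO-iTreg against TGFβ-iTreg, each with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene is limma's moderated test. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Gene positions are those of GENCODE M21 on GRCm38, and 226 of 234 named genes were matched by name.

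Gene lists covering Treg genes, T cell states, helper programmes, metabolism, stress, signalling and other cell types were fixed before the data were examined, as were the test, the threshold and the rule for naming genes. A list was tested when at least 4 members had enough signal, which held for 28 of 30. The camera test was run with a preset correlation between genes of 0.01 and with an estimated correlation, and fry as a further test, which passed 19, 20 and 15 lists in the order of the contrasts. Genes were named by a rule with 4 parts, per contrast. The first took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 20 in the higher group and no overlap between the 3 and 3 libraries, without predicted models and pseudogenes. The second took up to 4 called members of each list with the largest changes. The third was a set of Treg, cytokine and T cell genes named in advance, given whatever their result. The fourth took the 10 genes per direction with the largest difference of mTO-iTreg cells from both other groups, with the same filters. eGFP was added as the reporter and Xist as a check. Marker lists of other cells were tallied by library, and single list members that moved against their list (Atf4, Txnip, Pdk1, Ier3, Ddit4), the mitochondrial RNAs by class and the Y-linked gene Uba1y were chosen after their values were seen.

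Genes called in both contrasts against day 0 were compared with independent lists and with 100 simulated draws in which no group differed, since both contrasts share the day 0 libraries. In simulated data, 2-fold and 4-fold changes were planted in 200 genes with a mean of at least 20, in both directions. Of 2-fold changes 59%, 49% and 44% were called in the 3 contrasts, and of 4-fold changes 90%, 94% and 89%. Of the calls, 5.70%, 2.72% and 1.48% were false. These shares do not cover rarer genes, errors of scaling or the larger share of genes called in the data.

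Alternatives changed 1 choice at a time: pseudocounts of 0.5 and 5, no filter, a filter at 20, TMM factors (trimming 30% of log ratios and 5% of mean levels), equal totals, quantile normalization, fits of 2 groups, a replicate block, no variance trend, array weights, a log2 change of at least 1, and leaving out each library in turn. Added after the data were seen were limma-voom on recovered counts, thinning to the smallest library, scaling without mitochondrial genes and Rn45s, and leaving out the shallowest day 0 and TGFβ-iTreg libraries. Replicate numbers were not used as pairs, because same-number libraries had small correlations once group means were removed (-0.05 to 0.06), although 3 of 9 were closest to their own number.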

Results

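The data were gene counts from CD4+ T cells of a reporter mouse strain in which eGFP is made from the locus of Foxp3, the transcription factor that defines regulatory T cells (Treg cells). There were 9 libraries in 3 groups of 3. The first group was eGFP-negative CD4+ T cells taken on day 0. The second was eGFP-positive cells from day 5 of culture with 10 ng/ml TGFβ, 300 U/ml IL-2 and antibodies to CD3 and CD28 at 1 µg/ml (induced Treg cells, TGFβ-iTreg). The third was eGFP-positive cells from day 5 of co-culture with organoids, small self-organising cultures grown from mouse colorectal tumours (mTO-iTreg), with 20 U/ml IL-2 and the same antibodies; no added TGFβ is listed for it. The day 0 libraries held 3432420, 2267922 and 5328169 counts for replicates 1, 2 and 3, the TGFβ-iTreg libraries 2078223, 7222895 and 9944952, and the mTO-iTreg libraries 7551177, 7969853 and 7665711. A single count was worth between 0.494 and 2.69 normalized counts, depending on the library. Of 14912 genes in the table, 10983 had enough signal to be tested. Levels are given as mean normalized count ± SD over the 3 libraries of a group, and fold changes as the ratio of those means. Floors and counting intervals cover counting error only. The labels do not say whether libraries came from separate animals or cultures, so the p-values measure only the spread between these samples.

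The 3 groups were separate at the level of the whole transcriptome. The first principal component, with 39.7% of the variance, set the mTO-iTreg libraries (scores of 76.5 to 88.6) apart from the other 6 (-88.7 to -6.67). The second component, with 22.1%, separated TGFβ-iTreg from both other groups. Across genes, log2 values correlated at 0.906 or more within each group, at 0.830 to 0.896 between day 0 and TGFβ-iTreg, at 0.772 to 0.828 between day 0 and mTO-iTreg, and at 0.817 to 0.858 between the iTreg groups. The reporter transcript followed the sort. eGFP stood at 54.6 ± 30.3 on day 0, 652 ± 56.9 in TGFβ-iTreg and 343 ± 105 in mTO-iTreg cells, higher than on day 0 in both iTreg groups (adjusted p = 1.4e-05 and 4.8e-05). Foxp3 itself, at 7573644 to 7595245 on chromosome X, was read sparsely: 3.63 ± 4.58 on day 0, 16.5 ± 2.78 in TGFβ-iTreg and 62.6 ± 22.7 in mTO-iTreg cells, from 7, 60 and 284 counts in all.

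**Figure D1:**
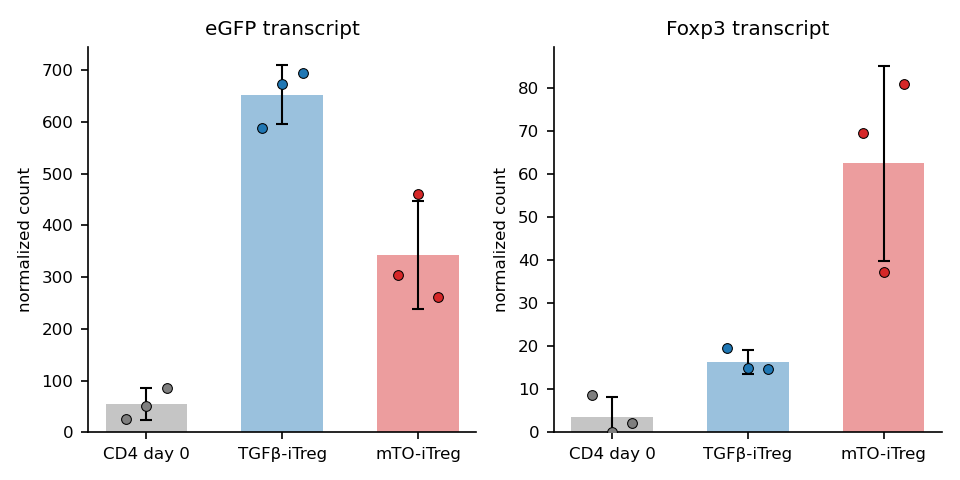
Normalized counts of the eGFP and Foxp3 transcripts in the 9 libraries (points), with the group mean (bars) and SD (error bars, n = 3). eGFP was highest in TGFβ-iTreg cells (652) and Foxp3 in mTO-iTreg cells (62.6).

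The comparison of TGFβ-iTreg with day 0 cells sets eGFP-positive cells after 5 days with TGFβ, IL-2 and antibodies beside eGFP-negative cells before culture, and these differences cannot be separated. TGFβ-iTreg cells had more transcripts of the core Treg, cell cycle and several metabolic lists, and fewer of the naive T cell and heat shock lists. Of 28 lists 14 passed by camera with a preset correlation, and none did with an estimated correlation (smallest adjusted p = 0.12). By limma's moderated test, 2040 genes changed (18.6% of those tested), 1074 upward and 966 downward, and 722 and 602 of them changed at least 2-fold. The share of upward calls depends on scaling. It was 52.6% with the deposited normalization, 75.5% with every library scaled to the same total (1793 up, 582 down) and 65.7% with libraries scaled on genes other than mitochondrial ones and Rn45s; those scalings moved the median log2 change of all genes from -0.02 to 0.23 and 0.11. Limma-voom on the recovered counts, added after the data were seen, turned the majority, with 616 up and 800 down (43.5% upward). So did leaving out TGFβ-iTreg replicate 2 (710.0 up, 726 down) or 3 (685 up, 717 down), and the fit of these 2 groups alone (941 up, 945 down). Leaving out the shallowest day 0 and TGFβ-iTreg libraries lowered the number of calls to 1166.

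Of 19 core Treg genes, 17 rose and none fell, and the counts were the same adjusted over the list alone (camera adjusted p = 3e-14 with a preset correlation between genes; adjusted p = 0.12 with an estimated correlation). Lrrc32, which presents latent TGFβ on the cell surface, rose 31.9-fold from 4.80 ± 4.16 to 153 ± 28.3 (log2 change 5.23 ± 0.65 SE, adjusted p = 0.00013; chromosome 7, 98489283 to 98502181). Il2ra, the high-affinity IL-2 receptor chain, rose 13.4-fold to 3651 ± 950.2. The inhibitory receptor Ctla4 rose by the same factor, 13.4-fold, to 884 ± 51.6 (adjusted p = 2e-06). Itgae, the integrin chain CD103 that binds epithelial E-cadherin, rose 14.5-fold to 519 ± 136, and Nt5e, the CD73 enzyme that makes adenosine, rose 6.49-fold to 2022 ± 358. Ikzf2 (3.94-fold) and Tnfrsf18 (2.60-fold) rose less. The rise of Foxp3, 4.54-fold (adjusted p = 0.04), rested on few counts: 12 of 25 alternative analyses ended the call, 7 of them by leaving out a single library, with adjusted p from 0.0094 to 0.21 over all 25. It was 0.11 and 0.069 without day 0 replicates 2 and 3, 0.10, 0.085 and 0.087 without TGFβ-iTreg replicates 1, 2 and 3, and 0.058 and 0.055 without mTO-iTreg replicates 1 and 3. In the effector Treg list, 6 of 17 members rose, Irf4 (5.72-fold) and Maf (3.66-fold) among them, and 7 rose and 1 fell adjusted over the list alone. That list passed only narrowly (adjusted p = 0.047; adjusted p = 0.27 with an estimated correlation) and lost its call under 8 of 25 alternatives (adjusted p from 0.024 to 0.25). For effector Treg genes it was 0.095 and 0.068 without day 0 replicates 1 and 2, 0.092 without TGFβ-iTreg replicate 2 and 0.063 without mTO-iTreg replicate 2.

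Of 33 cell cycle genes 25 rose, 26 adjusted over the list alone (adjusted p = 8.8e-14; adjusted p = 0.14 with an estimated correlation), for example Aurkb from 6.91 ± 10.5 to 151 ± 13.6 and Ccna2 from 28.3 ± 22.2 to 245 ± 23.7. IL-2 and STAT5 target genes rose in 10 of 17 cases, 12 adjusted over the list alone (adjusted p = 7e-06; adjusted p = 0.14 with an estimated correlation), with Socs2 up 15.3-fold to 3493 ± 1582, Cish up 6.81-fold and Gzmb, the cytotoxic protease granzyme B, up 15.6-fold to 564 ± 255. Cholesterol synthesis genes rose in 10 of 21 cases, 12 adjusted over the list alone (adjusted p = 2e-06; adjusted p = 0.14 with an estimated correlation), Sc5d by 3.26-fold and Fdps by 2.83-fold. Of 47 oxidative phosphorylation genes encoded in the nucleus, 20 rose and none fell, 21 adjusted over the list alone (adjusted p = 2e-06; adjusted p = 0.14 with an estimated correlation), each by a small factor such as 1.95-fold for Uqcr11. Glycolysis and hypoxia genes rose in 9 of 26 cases and fell in 2, or 11 and 2 adjusted over the list alone (adjusted p = 0.017; adjusted p = 0.28 with an estimated correlation), with Tpi1 up 2.37-fold and Pgam1 2.19-fold. NF-κB targets rose in 5 of 16 cases, as they did adjusted over the list alone (adjusted p = 0.006; adjusted p = 0.14 with an estimated correlation), led by the chemokine gene Ccl4 at 15.6-fold. Amino acid stress genes driven by ATF4 rose in 5 of 21 cases and 1, Atf4, fell, or 6 and 2 adjusted over the list alone (adjusted p = 0.011; adjusted p = 0.36 with an estimated correlation).

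Downward, 9 of 22 genes of naive and quiescent T cells fell and 1, Txnip, rose, or 10 and 1 adjusted over the list alone (adjusted p = 0.0066; adjusted p = 0.15 with an estimated correlation). Dapl1 fell 46.2-fold from 1802 ± 119 to 39.0 ± 19.1, and the transcription factors Lef1 and Tcf7 fell 3.05-fold and 3.02-fold. Heat shock and immediate early genes fell in 9 of 16 cases, 10 adjusted over the list alone, and none rose (adjusted p = 1.9e-05; adjusted p = 0.14 with an estimated correlation). Fos fell 17.9-fold from 3503 ± 905, and Hspa1b 49.8-fold from 4956 ± 697; Hspa1b and Hspa1a are near-identical copies, so the division of reads between them is uncertain. T cell identity genes fell in 9 of 16 cases and rose in none, or 11 adjusted over the list alone (adjusted p = 2.4e-05; adjusted p = 0.14 with an estimated correlation), with Cd4 down 2.44-fold to 1009 ± 36.8. Of 78 ribosomal protein genes, 22 fell and 2 rose, 24 and 2 adjusted over the list alone (adjusted p = 0.0016; adjusted p = 0.5 with an estimated correlation); the list's median was -0.20 here and 0.065 under quantile normalization, where the call ended (adjusted p = 0.44), as it did with equal totals (adjusted p = 0.33, within a range of 5.1e-08 to 0.44 over 25 alternatives). Mitochondrially encoded RNAs fell in 11 of 32 cases, all of them mRNAs, and rose in none, with the same counts adjusted over the list alone (adjusted p = 0.01; adjusted p = 0.28 with an estimated correlation), though quantile normalization ended that call (adjusted p = 0.22, within 1.4e-06 to 0.22).

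Interferon-inducible genes moved both ways: 11 of 37 rose and 9 fell, or 13 and 12 adjusted over the list alone. The list did not pass, and its median (-0.05) and mean (-0.13) were negative while the test pointed up (adjusted p = 0.81). The guanylate-binding protein gene Gbp2 rose 8.65-fold to 9379 ± 2184 (chromosome 3, 142620602 to 142638008), whereas the antiviral gene Ifit2 fell 6.76-fold. TGFβ response genes rose in 6 of 17 cases and fell in 3, the same adjusted over the list alone (adjusted p = 0.36), with Pmepa1 up 10.3-fold and the accessory receptor Tgfbr3 down (log2 change -2.55). The largest rises of single genes under the rule fixed beforehand included Ckap2 (49.8-fold), Src (29.5-fold, from 6.21 ± 9.28 to 183 ± 20.2) and Plekhd1, which was at 0 on day 0 and at least 32.0-fold higher in TGFβ-iTreg cells against a floor of 3 counts over the group. The largest falls included Sema4a (36.3-fold) and Dtx1 (42.8-fold). Of 12 tested myeloid and antigen-presenting genes, 9 were highest, among the day 0 libraries, in replicate 3, and 5 fell in TGFβ-iTreg cells while 1 rose. H2-Ab1 stood at 588, 293 and 2463 on day 0 and at 66.1 ± 29.2 in TGFβ-iTreg cells. Day 0 replicate 3 also held 212 of Xist, against 3.51 and 0 in the other 2.

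**Figure D2:**
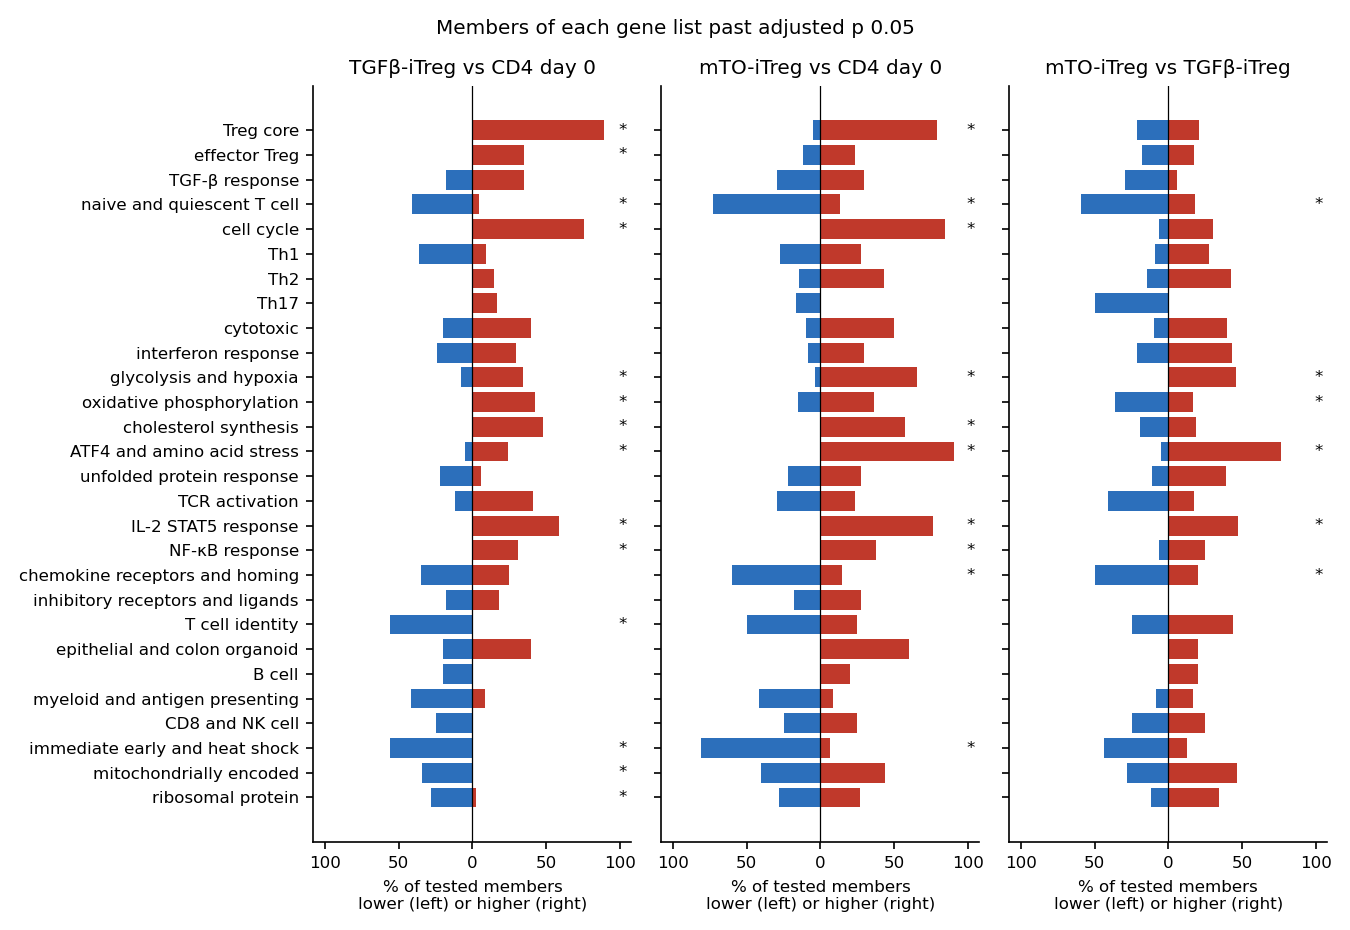
Share of each list's tested members that were higher (red, to the right) or lower (blue, to the left) past an adjusted p of 0.05, in percent, for the 28 tested lists and 3 comparisons; an asterisk marks lists past the same threshold by camera with a preset correlation. 14, 10 and 6 lists passed, and none passed with an estimated correlation.

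The comparison of mTO-iTreg with day 0 cells sets eGFP-positive cells after 5 days with tumour organoids, IL-2 and antibodies beside the same eGFP-negative cells. The form of the library codes also differed between these groups, so none of these differences can be separated. Here 3723 genes changed (33.9%), 2126 upward and 1597 downward, with 1590 and 1016 of them at least 2-fold. This was the largest count of the 3 comparisons, but limma-voom on the recovered counts turned that order (3416 genes here and 3723 between the iTreg groups). The core Treg, cell cycle, IL-2, glycolysis and ATF4 lists rose, and the naive, heat shock and homing lists fell, with a preset correlation. None of the 10 lists that passed did so with an estimated correlation (adjusted p = 0.11 to 0.18). With libraries scaled to equal totals, 70.6% of calls were upward in place of 57.1% (2739 up, 1141 down), and the median log2 change of all genes was 0.31 in place of 0.09; with scaling on genes other than mitochondrial ones and Rn45s it was 0.21 (64.9% upward). TMM factors gave 52.4% upward, and quantile normalization turned the majority (1892 up, 1971 down, 49.0% upward, median -0.07).

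Of 19 core Treg genes 15 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 2.2e-07; adjusted p = 0.11 with an estimated correlation). Foxp3 rose 17.3-fold (log2 change 4.28 ± 0.77 SE, adjusted p = 0.00079, and between 0.00018 and 0.0085 under 25 alternatives). Lrrc32 rose 73.0-fold to 350.2 ± 116, Tnfrsf9, the costimulatory receptor 4-1BB, 30.2-fold to 1338 ± 153, and Tnfrsf4, the receptor OX40, 20.0-fold to 878 ± 131. Ikzf2, which encodes the Treg transcription factor Helios, rose 13.1-fold to 868 ± 132 (chromosome 1, 69531214 to 69687245) and Tnfrsf18, the receptor GITR, 8.49-fold to 1976 ± 171. The member that fell was Itgae, 3.49-fold to 10.3 ± 8.31 (adjusted p = 0.02), a call that 4 of 25 alternatives ended (from 0.0047 to 0.07), among them leaving out day 0 replicate 3 (0.07). In the effector Treg list 4 of 17 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.52), among them Ebi3, a subunit of IL-35 and IL-27, at 109 ± 22.8 with 2 counts in all on day 0.

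The strongest list by share of members was that of ATF4 targets: 19 of 21 rose and none fell, also adjusted over the list alone (adjusted p = 9.5e-09; adjusted p = 0.11 with an estimated correlation). Asns, asparagine synthetase, was at 242 ± 18.9 with 2 counts on day 0 (adjusted p = 2.5e-06; chromosome 6, 7675169 to 7693254), and Chac1, a glutathione-degrading enzyme, was at least 53.5-fold higher, with 0 counts on day 0. Glycolysis and hypoxia genes rose in 17 of 26 cases and 1, Pdk1, fell, or 18 and 1 adjusted over the list alone (adjusted p = 2.2e-06; adjusted p = 0.11 with an estimated correlation); Aldoc rose 45.4-fold to 1218 ± 90.8, Vegfa 10.6-fold, and the hypoxia-induced carbonic anhydrase Car9 was at least 13.8-fold higher. IL-2 and STAT5 targets rose in 13 of 17 cases, 14 adjusted over the list alone (adjusted p = 8.7e-07; adjusted p = 0.11 with an estimated correlation), led by Cdkn1a, the cell cycle inhibitor p21, which rose 518-fold from 5.66 ± 5.81 to 2931 ± 767 (chromosome 17, 29090976 to 29100727). Gzmb rose 142-fold to 5127 ± 788 (chromosome 14, 56258838 to 56262260). In spite of Cdkn1a, 28 of 33 cell cycle genes rose and none fell, also adjusted over the list alone (adjusted p = 3.8e-11; adjusted p = 0.12 with an estimated correlation), with Tpx2 up 37.4-fold. Cholesterol synthesis genes rose in 12 of 21 cases, also adjusted over the list alone (adjusted p = 0.00061; adjusted p = 0.18 with an estimated correlation), and NF-κB targets in 6 of 16, also adjusted over the list alone (adjusted p = 0.018; adjusted p = 0.18 with an estimated correlation), with Bcl3 up 5.92-fold.

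Naive and quiescent T cell genes fell in 16 of 22 cases and rose in 3, or 17 and 3 adjusted over the list alone (adjusted p = 2.2e-06; adjusted p = 0.11 with an estimated correlation). Il7r, the receptor for the survival cytokine IL-7, fell 5.11-fold to 305 ± 27.7. Immediate early and heat shock genes fell in 13 of 16 cases and 1, Ier3, rose, also adjusted over the list alone (adjusted p = 4.4e-06; adjusted p = 0.11 with an estimated correlation); Hspa1b fell from 4956 ± 697 to 7.84 ± 0.928. Chemokine receptors and homing molecules fell in 12 of 20 cases and rose in 3, or 13 and 4 adjusted over the list alone (adjusted p = 0.0089; adjusted p = 0.18 with an estimated correlation), with Cxcr6 down to 4.73 ± 6.54 from 250.3 ± 116 and the gut-homing receptor Ccr9 up 8.20-fold to 972 ± 156. That list lost its call only with the shallowest day 0 and TGFβ-iTreg libraries left out (adjusted p = 0.081, within 0.0043 to 0.081 over 25 alternatives). The largest rises included the lipocalin genes Lcn10, up 398-fold to 4190.0 ± 741, and Lcn6, at least 391-fold higher than on day 0, and Psrc1, at 789 ± 209.5 with 3 counts on day 0. The largest falls included Klrd1 (96.8-fold) and Susd2 (54.0-fold). TGFβ response genes split evenly, 5 of 17 up and 5 down, also adjusted over the list alone, with a negative median (-0.30), a positive mean (0.10) and a test that pointed down (adjusted p = 0.55).

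The genes shared by both inductions were counted next. Both iTreg groups differed from day 0 in the same direction in 1128 genes, 664 higher and 464 lower, and in opposite directions in 98. Independent lists of the same sizes would share 208 and 140.5. Unchanged groups simulated against shared day 0 libraries shared 0.01 genes on average and 1 at most. With no gene changed hardly any could be called, so that small count was fixed in advance and bears little on the 1128. The log2 changes had a covariance of 0.929, against 0.163 from simulated noise in the shared libraries. The difference, 0.765, covers whatever both contrasts share, any bias of the day 0 libraries included. Across genes, which are not independent replicates, the correlation of the log2 changes was 0.557, against 0.4995 in the simulation. Both changes had the same sign in 67.9% of genes, against 66.6% in the simulation. The day 0 libraries were too few to split, so part of the excess over independent lists may come from sharing them. The number of shared genes fell to 726 when the shallowest day 0 and TGFβ-iTreg libraries were left out. Lrrc32, Il2ra, Ctla4, Tnfrsf18 and Ikzf2 were among the shared rises, and Dapl1, Tcf7, Fos and Hspa1b among the shared falls.

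The comparison of mTO-iTreg with TGFβ-iTreg asks whether organoids give a Treg population apart from the one TGFβ gives, which is the question of the series title. The iTreg groups differed in 2924 genes (26.6%), 1632 higher in mTO-iTreg cells and 1292 lower, with 1164 and 738 of them at least 2-fold. Which direction held the majority depends on scaling: 55.8% of calls were upward here, 48.6% with TMM factors (1400.0 up, 1483 down) and 46.7% with quantile normalization (1419 up, 1622 down), and the median log2 change of all genes was 0.13, 0.04 and -0.04. mTO-iTreg cells had more transcripts of the ATF4 and glycolysis lists, Gzmb, Tnfrsf9 and Tnfrsf18, and TGFβ-iTreg cells had more of Itgae, Nt5e, Nrp1, Maf and Gbp2. None of the 6 lists that passed did so with an estimated correlation (smallest adjusted p = 0.41). IL-2 dose, TGFβ and the form of the library codes all differed between these groups, so their contributions cannot be separated.

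Core Treg genes did not differ as a list: 4 of 19 were higher and 4 lower, or 5 and 6 adjusted over the list alone, with a positive median (0.25), a negative mean (-0.11) and a test that pointed up (adjusted p = 0.97). Ctla4 was at 829.5 ± 137 in mTO-iTreg and 884 ± 51.6 in TGFβ-iTreg cells (adjusted p = 0.8), and Il2ra at 2398 ± 164 and 3651 ± 950.2 (adjusted p = 0.28, from 0.021 to 0.57, with 3 of 25 alternatives calling it). Higher in mTO-iTreg cells were Tnfrsf9 (8.37-fold), Ikzf2 (3.33-fold, log2 change 1.81 ± 0.27 SE, adjusted p = 0.00031) and Tnfrsf18 (3.27-fold). Lower were Itgae, by 50.4-fold (10.3 ± 8.31 against 519 ± 136, adjusted p = 1.9e-05; chromosome 11, 73090583 to 73147446), Nt5e, by 5.33-fold (chromosome 9, 88327197 to 88372092), and the semaphorin receptor Nrp1, by 6.39-fold. Foxp3 was 3.801-fold higher by its mean but did not pass (adjusted p = 0.1, from 0.0081 to 0.39 over 25 alternatives, 6 of which called it), and eGFP was 1.90-fold lower and did not pass either (adjusted p = 0.053, from 0.002 to 0.16, with 11 alternatives calling it). Effector Treg genes went both ways, 3 of 17 up and 3 down, also adjusted over the list alone, with a positive median (0.18) and mean (0.13) and a test that pointed down (adjusted p = 0.67); Maf was 13.7-fold and Irf4 3.40-fold lower in mTO-iTreg cells.

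ATF4 targets were higher in 16 of 21 cases and 1, Ddit4, was lower, also adjusted over the list alone (adjusted p = 3.2e-06; adjusted p = 0.41 with an estimated correlation), with Asns 24.6-fold and Chac1 41.8-fold higher. Glycolysis and hypoxia genes were higher in 12 of 26 cases and lower in none, also adjusted over the list alone (adjusted p = 0.0012; adjusted p = 0.41 with an estimated correlation), with Aldoa 3.34-fold and the glucose transporter Slc2a3 5.09-fold higher. Naive T cell genes were lower in 13 of 22 cases and higher in 4, also adjusted over the list alone (adjusted p = 0.018; adjusted p = 0.41 with an estimated correlation), with Klf2 4.02-fold and Il6ra 4.02-fold lower, and Dapl1 7.46-fold higher; quantile normalization ended that call (adjusted p = 0.10, within 0.0081 to 0.10). IL-2 and STAT5 targets were higher in 8 of 17 cases, with 8 higher and 1 lower adjusted over the list alone (adjusted p = 0.042; adjusted p = 0.64 with an estimated correlation), although the IL-2 dose was lower. Cdkn1a was 110.5-fold and Bcl2l1 3.76-fold higher. Leaving out day 0 replicate 1 (0.055) or TGFβ-iTreg replicate 2 (0.074), or adding a replicate block (0.054), ended this call, with adjusted p from 0.0044 to 0.074 over 25 alternatives. Nuclear oxidative phosphorylation genes were lower in 17 of 47 cases and higher in 8, or 17 and 10 adjusted over the list alone (adjusted p = 0.047; adjusted p = 0.64 with an estimated correlation), a narrow call that 10 alternatives ended, among them leaving out day 0 replicate 1 (0.055), TGFβ-iTreg replicate 1 (0.095), or mTO-iTreg replicate 1 (0.091) or 2 (0.078), with adjusted p from 0.018 to 0.45. Homing receptors were lower in 10 of 20 cases and higher in 4, or 10 and 5 adjusted over the list alone (adjusted p = 0.048; adjusted p = 0.64 with an estimated correlation), with Cxcr3 7.49-fold lower and Cxcr5 21.3-fold higher. Of 25 alternatives 19 ended that call (adjusted p from 0.033 to 0.20), 8 of them by leaving out 1 library: 0.062, 0.10 and 0.058 without day 0 replicates 1, 2 and 3, 0.13, 0.053 and 0.066 without TGFβ-iTreg replicates 1, 2 and 3, and 0.052 and 0.062 without mTO-iTreg replicates 1 and 3. The replicate block also ended the calls of the oxidative phosphorylation and homing lists (adjusted p = 0.054 for each). With the block, and also without day 0 replicate 1, only 3 of the 6 lists passed.

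**Figure D3:**
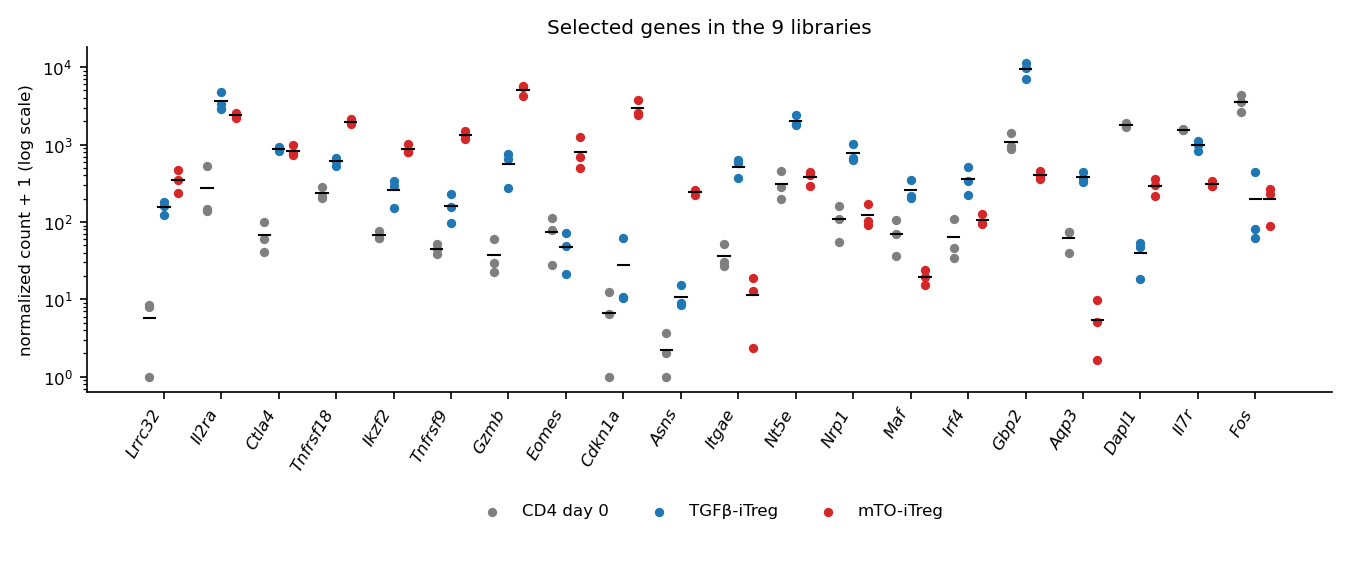
Normalized count plus 1, on a log scale, of 20 genes in the 9 libraries (points, coloured by group) with group means (bars). Gzmb, Cdkn1a, Asns and Ikzf2 were highest in mTO-iTreg cells, and Itgae, Nt5e, Nrp1, Maf and Gbp2 were highest in TGFβ-iTreg cells.

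None of 11 inhibitory receptors and ligands passed between the iTreg groups. Cell cycle genes, 10 of 33 higher and 2 lower, also adjusted over the list alone, did not pass as a list (adjusted p = 0.15, from 0.011 to 0.33, with 4 of 25 alternatives calling it). Immediate early and heat shock genes, 2 of 16 higher and 7 lower, also adjusted over the list alone, did not pass (adjusted p = 0.056, from 0.012 to 0.27, with 14 of 25 alternatives calling the list). NF-κB targets did not pass either (4 of 16 higher and 1 lower), with a positive median (0.22), a negative mean (-0.09) and a test that pointed up. Helper and cytotoxic genes were mixed. Gzmb was 9.09-fold higher in mTO-iTreg cells and the T-box factor Eomes 17.3-fold (808 ± 389 against 46.6 ± 25.6). Of cytotoxic genes, 4 of 10 were higher and 1 lower, or 5 and 3 adjusted over the list alone, and the list did not pass (adjusted p = 0.23). The chemokine gene Ccl20 had no counts in mTO-iTreg cells and was at least 43.5-fold lower than its 28.5 ± 16.6 in TGFβ-iTreg cells; 3 of 6 type 17 genes were lower and none higher, also adjusted over the list alone (adjusted p = 0.15). Gata3 was 2.34-fold higher at 951 ± 109, whereas Tbx21 (adjusted p = 0.91), Ifng (0.64), Lag3 (0.25) and Tgfb1 (0.31) did not pass. Il10 was barely read, with 0, 10 and 16 counts in all on day 0, in TGFβ-iTreg and in mTO-iTreg cells. Of 37 interferon-inducible genes 16 were higher and 8 lower, also adjusted over the list alone (adjusted p = 0.26). The antiviral gene Rsad2 was at 53.1 ± 12.4 against 3 counts in all, while Gbp2 was 23.4-fold and Gbp3 14.04-fold lower. Outside that list, Gbp1 was at least 166-fold lower and Stat4, the IL-12 signalling factor, 4.21-fold higher. TGFβ response genes were lower in 5 of 17 cases and higher in 1, or 6 and 1 adjusted over the list alone, and did not pass (adjusted p = 0.096, from 0.03 to 0.17, with 2 of 25 alternatives calling the list). The receptor Tgfbr1 was 3.08-fold lower and Klf10 8.97-fold higher. The largest differences upward included the transglutaminase gene Tgm2, at 378 ± 57.6 with 2 counts in TGFβ-iTreg cells, and downward the glycerol channel Aqp3 (84.7-fold), Igfbp7 (85.6-fold), Ccl4 (61.2-fold) and Bdh2 (at least 195-fold).

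Genes that set 1 group apart from both others were counted last. In mTO-iTreg cells 1800 genes differed from both other groups in the same direction, 992 higher and 808 lower, against 629 in TGFβ-iTreg cells (295 and 334) and 1128 in day 0 cells (464 and 664). The mTO-iTreg libraries were also the only ones with the other form of library code, which cannot be separated from the group. The TGFβ-iTreg count was 390 without TGFβ-iTreg replicate 1, and the count for mTO-iTreg ranged from 1320 to 1735 with 1 library left out. Cdkn1a, Tgm2 and Lcn6 were apart upward in mTO-iTreg cells, and Crmp1, S100a4 and Rasgrp3 downward. S100a4, a calcium-binding protein of memory T cells, stood at 217 ± 111, 300.2 ± 310.2 and 6.18 ± 2.27 in day 0, TGFβ-iTreg and mTO-iTreg cells.

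Mitochondrially encoded RNAs differed by class in the mTO-iTreg libraries. They took 18.6% ± 1.13 of counts on day 0, 11.6% ± 1.02 in TGFβ-iTreg and 12.3% ± 0.145 in mTO-iTreg libraries, but the ribosomal RNAs among them took 2.22% ± 0.855, 1.86% ± 0.297 and 7.11% ± 0.336 of counts. Against TGFβ-iTreg, 8 of 13 mitochondrial mRNAs were lower and 2 higher (median log2 change -1.35), whereas 11 of 17 transfer RNAs were higher and 1 lower (median 3.69). Many of these transfer RNAs, mt-Tc, mt-Ts2, mt-Tp, mt-Tq and mt-Tr among them, passed the filter only through the mTO-iTreg libraries. With 1 mTO-iTreg library left out, 22 or 23 of the 32 mitochondrial RNAs were still tested. The count and median of the transfer RNAs therefore lean upward by selection. The cytochrome b mRNA mtCytb changed by -2.61 log2, while mtNd6 changed by 2.55 and mt-Tc by 8.57. Taken as a list of 32, 15 were higher and 9 lower, or 16 and 10 adjusted over the list alone (adjusted p = 0.26); against day 0 it was 14 and 13, or 16 and 13 (adjusted p = 0.73, from 0.0039 to 0.95 over 25 alternatives). Without mTO-iTreg replicate 1, 2 or 3 the mitochondrially encoded list passed as lower than on day 0 (adjusted p = 0.0051, 0.0039 and 0.012), with 22, 22 and 23 members tested. Ribosomal protein genes also went both ways, 27 of 78 higher and 9 lower than in TGFβ-iTreg, or 29 and 9 adjusted over the list alone (adjusted p = 0.26, from 0.017 to 0.67, with 2 of 25 alternatives calling the list), and 21 higher and 22 lower than on day 0, or 23 and 24 (adjusted p = 0.48). Under quantile normalization the ribosomal protein list passed as higher than on day 0 (adjusted p = 0.0052, within 0.0052 to 0.89), and its median turned from -0.08 to 0.20.

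**Figure D4:**
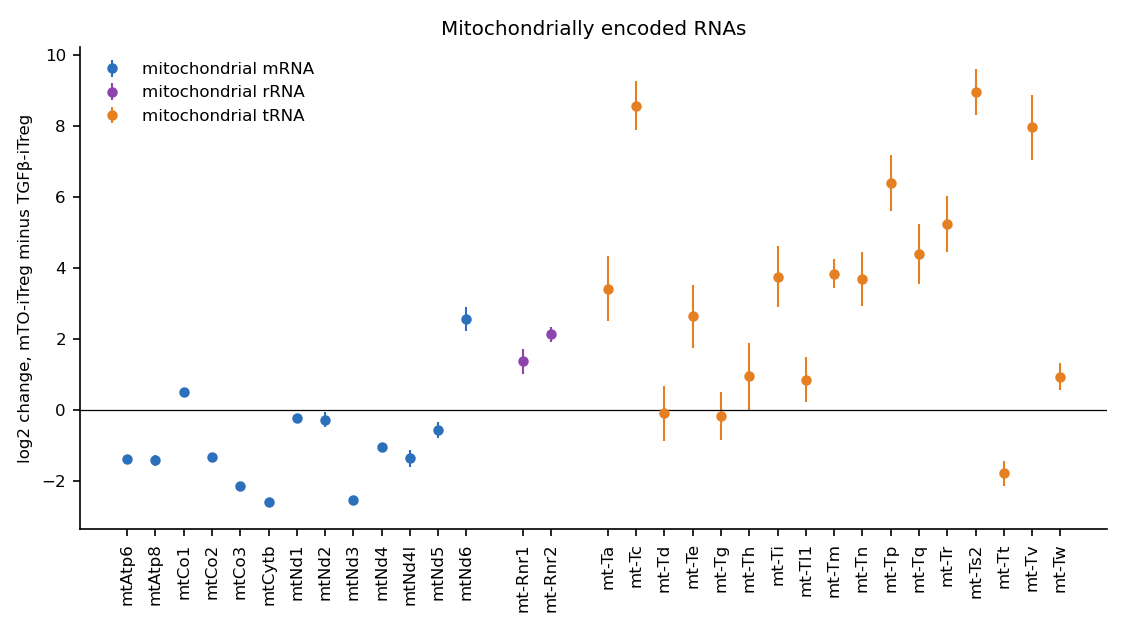
Log2 change, mTO-iTreg minus TGFβ-iTreg, of each tested mitochondrially encoded RNA (points) with its standard error (bars), by class. Most mRNAs lay below 0, with mtNd6 and mtCo1 above it; both ribosomal RNAs lay above 0, as did most transfer RNAs, up to 8.96 for mt-Ts2.

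Markers of other cells were examined by list. Of 34 epithelial and colon organoid genes 19 had a row and 5 enough signal to test. Epcam, the epithelial adhesion gene, was at 10.5 ± 7.29 on day 0, 93.4 ± 19.2 in TGFβ-iTreg and 48.1 ± 36.0 in mTO-iTreg cells. It did not pass between the iTreg groups (adjusted p = 0.16, from 0.041 to 0.44 over 25 alternatives, 1 of which called it). None of the epithelial, B cell, myeloid and CD8 or NK lists passed in any comparison by camera with the main choices. Of the 5 tested epithelial genes, Cdh1 and Epcam were higher and Spint2 lower in TGFβ-iTreg cells than on day 0, and all 3 were higher in mTO-iTreg cells, with the same counts adjusted over the list alone. By fry, which does not compare a list with other genes, the epithelial list passed in both (adjusted p = 0.048 and 0.0027) and between the iTreg groups (0.047). In mTO-iTreg cells the rise of Cdh1 (adjusted p = 0.023, from 0.01 to 0.13 over 25 alternatives) lost its call without day 0 replicate 2 (0.072) or mTO-iTreg replicate 1 (0.058) or 3 (0.09). That of Epcam (adjusted p = 0.016, from 0.0059 to 0.09) lost it without day 0 replicate 1 (0.057) or mTO-iTreg replicate 3 (0.088). Of 12 tested members of the myeloid list, 5 fell and 1 rose in each iTreg group against day 0, or 6 and 1 (TGFβ-iTreg) and 5 and 1 (mTO-iTreg) adjusted over the list alone: adjusted p = 0.076 in TGFβ-iTreg cells, with 9 of 25 alternatives calling it (0.014 to 0.31), and 0.074 in mTO-iTreg cells, with 10 calling it (0.03 to 0.41). H2-Eb1, of that list, was at 2331, 1410.0 and 1817 in the mTO-iTreg libraries and at 344, 175 and 1985 on day 0. Between the iTreg groups the epithelial list had a negative median (-0.79), a positive mean (0.15) and a test that pointed up, and the myeloid list a positive median (0.16) and mean (0.21) and a test that pointed down. Xist was read in every mTO-iTreg library (314, 398 and 401) and, in the other groups, mainly in replicate 3 (212 on day 0 and 70.6 in TGFβ-iTreg). Foxp3, Ctla4, Itgae, Ikzf2, Tnfrsf18, Tnfrsf9, Maf, Ebi3, Ccna2, Cish, Fdps, Tpi1, Lef1, Tcf7, Hspa1a, Tgfbr3, Xist, Car9, Bcl3, Cxcr6, Cxcr5, Ccr9, Aldoa, Slc2a3, Il6ra, Eomes, Gata3, Stat4, Tgm2, Igfbp7, Crmp1, S100a4, H2-Eb1 and mt-Ts2 overlap another annotated gene, and whether strand was used in counting is not given in the sources used here, so their values could include reads of that neighbour. The guanylate-binding proteins belong to a family of similar sequence and carry the same doubt.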

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

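The tests of more mitochondrial RNA and of counting error in Foxp3, the thinned libraries, and the look at Uba1y were chosen after the results were seen; the others were written before their values were known.

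A group of 17 named genes moved in opposite directions against day 0 in the 2 inductions, and among all tested genes there were 98 of this kind. The difference between the iTreg groups was also called by limma for each. Genes picked for opposite changes differ between these groups by their selection, so that test adds no support. Higher in TGFβ-iTreg and lower in mTO-iTreg cells were Gbp1 (log2 change, mTO-iTreg minus TGFβ-iTreg, of -6.68), Igfbp7 (-6.62), Aqp3 (-6.44), Itgae (-5.94), Gbp2 (-4.53), Maf (-3.69), Ctss (-1.50) and Atp5j (-1.17). Lower in TGFβ-iTreg and higher in mTO-iTreg cells were H2-Eb1 (4.72), Usp18 (2.95), Stat4 (2.12), Cd4 (1.70), Cd2 (1.59), Spint2 (1.54), Herpud1 (1.20), Rps16 (1.14) and Hspa5 (1.09). Igfbp7, Itgae, Maf, Ctss, Atp5j, H2-Eb1, Usp18, Stat4 and Herpud1 overlap another annotated gene, so their values could include its reads. Not every change of these genes against day 0 was refitted, and of those refitted some lost their call when 1 library was left out. For H2-Eb1 in mTO-iTreg cells the adjusted p was 0.13 and 0.18 without day 0 replicates 1 and 2, and 0.11, 0.059 and 0.086 without mTO-iTreg replicates 1, 2 and 3 (0.00033 to 0.18 over 25 alternatives). For Usp18 in mTO-iTreg cells it was 0.14 without day 0 replicate 3, and 0.13 and 0.078 without mTO-iTreg replicates 2 and 3 (0.01 to 0.14). For Herpud1 in TGFβ-iTreg cells it was 0.096 and 0.077 without day 0 replicates 1 and 2, and 0.092, 0.058 and 0.074 without TGFβ-iTreg replicates 1, 2 and 3 (0.029 to 0.19). For Itgae in mTO-iTreg cells it was 0.07 without day 0 replicate 3 (0.0047 to 0.07).

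The first pattern weighed is the rise of mitochondrial transfer RNAs in the mTO-iTreg libraries. A rise of all mitochondrial RNA alike is argued against, since the mitochondrial mRNAs changed by a median of -1.35 (bootstrap interval over genes -1.43 to -0.29). The mitochondrial ribosomal RNAs took a larger share in mTO-iTreg than in TGFβ-iTreg libraries (7.11% against 1.86%), so more of some classes stays open. With all libraries thinned to the smallest total, the median rise of the transfer RNAs was 3.66 (1.24 to 5.75). The rise thus remained at equal depth for the tested members. Many of them passed the filter only through the mTO-iTreg libraries, so that median and interval lean upward and cannot decide on depth for the class. Capture of RNA without a poly(A) tail cannot be told apart from biology: 18 nuclear RNAs of that kind changed by a median of 0.44 (0.10 to 1.11), an interval that reaches past the bound of 1 set for it. Library preparation also stays open, because the library codes differ between the mTO-iTreg group and the others.

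The second pattern is Xist in all mTO-iTreg libraries (314, 398 and 401) and mainly in replicate 3 of the other groups. Donor mice of another sex may be the source, but 5 genes that escape X inactivation changed by a median of 0.28 (-0.83 to 0.81), which decides nothing with so few genes. Of these 3 changed upward. The only 1 called, Eif2s3x, was lower in mTO-iTreg cells (log2 change -0.83, limma adjusted p = 0.0036), against that direction. The Y-linked gene Uba1y had 16 counts on day 0, 14 in TGFβ-iTreg and 2 in mTO-iTreg libraries. Its normalized values were 14.0, 13.4 and 3.16 on day 0, and 2.46, 3.39 and 3.95 in TGFβ-iTreg libraries. They were 0, 1.24 and 0 in mTO-iTreg libraries, each below every other library, the direction that donors of another sex would give. That order rests on scaling, since mTO-iTreg replicate 2 held 2 counts and TGFβ-iTreg replicate 1 held 1. Of 2 rows on the Y chromosome, only Uba1y is given here. Within the TGFβ-iTreg group, however, replicate 3 was highest in both Xist and Uba1y. A gene read this rarely does not settle the sex of the donors. The labels call the mice hemizygous for the X-linked reporter and give no sex. A difference in sex between groups was not part of the stated design, and it cannot be told apart from the culture.

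The third pattern is the ratio of Foxp3 to its reporter. TGFβ-iTreg libraries held 44.0 eGFP counts for each Foxp3 count and mTO-iTreg libraries 5.58, an odds ratio of 7.88 (counting interval 5.90 to 10.67). Counting error of few Foxp3 reads is argued against by Fisher's exact test on the summed counts (p = 5.12e-61) and by library ratios that did not overlap between the groups. Summed counts leave out the spread between libraries. The mTO-iTreg libraries held 4.38, 12.4 and 3.23 eGFP counts per Foxp3 count, and the TGFβ-iTreg libraries 29.9, 45.2 and 46.9. What stays open, untested, is where reads fall relative to the transcript end that the reporter shares with Foxp3, and a difference in library preparation. Reads of annotated genes that overlap Foxp3 stay open too.

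Chance was examined by regrouping libraries. The 10 splits of 6 libraries into 3 and 3 cannot give a share under 0.05: the real splits gave 2040, 3723 and 2924 genes, with 1 split reaching that many in each contrast (the real one) and 0 genes as the highest other. For lists, the real splits gave 14, 10 and 6, reached by 1, 1 and 2 of the 10 splits, with 8, 9 and 6 as the highest others. Of 100 regroupings of all 9 libraries, 4 gave at least the 1128 genes shared by both contrasts against day 0, the real one included. The 3 others (1192 at most) each had the mTO-iTreg libraries as the group set against the rest. The count thus reflects how far a group lies from the others. Its rank therefore cannot decide on chance or on a response shared by both inductions. Only 1 of 100, the real one, gave 1800 genes apart in mTO-iTreg cells, with 1192 as the highest other. The regroupings with 1192 and 1178 genes also had all 3 mTO-iTreg libraries as the group set apart. This count too reflects how far those libraries lie from the rest, so its rank cannot decide on chance.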

How the results depend on the processing

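Limma-voom, thinning, scaling without mitochondrial genes and Rn45s, and leaving out the shallowest day 0 and TGFβ-iTreg libraries were chosen after the results were seen. Of the values of called named genes under the alternatives, 8297 kept their direction and call, 419 lost the call and 0 reversed; of those of called lists, 705 kept both, 44 lost the call and 1 reversed. Of values not called, 60 for lists and 46 for named genes gained a call, and 4 for lists reversed. With a log2 change of at least 1 also required, which by construction keeps fewer genes, TGFβ-iTreg against day 0 had 1324 genes, mTO-iTreg against TGFβ-iTreg 1902, the shared genes were 675 and those apart in mTO-iTreg cells 1078. Without a variance trend TGFβ-iTreg against day 0 had 1355 genes; the cause was not tested. Without the 2 shallowest libraries it had 1166 and the shared genes were 726, with fewer samples. With the replicate block, 1938, 3670 and 2838 genes passed and 3 lists in place of 6 for mTO-iTreg against TGFβ-iTreg (the IL-2, oxidative phosphorylation and homing lists lost their calls); correlations of same-number libraries were small (-0.05 to 0.06), so no pairing is established.

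Leaving out 1 library gave 1402 to 2020, 2972 to 3744 and 2149 to 3155 genes in the 3 contrasts, and 3 (without CD4 day 0 replicate 1) to 7 lists for mTO-iTreg against TGFβ-iTreg; it gave 826 to 1059 shared genes and 1320 to 1735 apart. The ribosomal protein list reversed under quantile normalization, to medians of 0.065 (TGFβ-iTreg against day 0) and 0.20 (mTO-iTreg against day 0, where it passed as higher, adjusted p = 0.0052); the cause was not tested. The mitochondrially encoded list, mTO-iTreg against day 0, ranged from -1.19 to 1.32 with 1 library left out; without any 1 mTO-iTreg library it turned negative and passed as lower (adjusted p from 0.0039 to 0.012), when 22 or 23 of 32 members were tested, because transfer RNAs at 5 or more in only 3 libraries then miss the filter. Depth limits rarely read genes: thinned to the smallest library, 1749, 3381 and 2605 genes passed, and voom gave 1416, 3416 and 3723, which turns the order of the last 2 contrasts. The 2 planned count models were not run, although counts were recovered, because the file check used here could not read decimal commas and so refused these models.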

Other observations

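The list of unseen p53 targets was drawn up after Cdkn1a and Psrc1 were seen and before the listed genes were looked at; every test here was set before its own value was known.

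Against day 0, mTO-iTreg cells joined a strong rise of the cell cycle inhibitor Cdkn1a to raised cell cycle genes (camera adjusted p = 3.8e-11 with a preset correlation only). That list rose in TGFβ-iTreg cells too (8.8e-14) and did not pass between the iTreg groups (0.15). Klf10, induced by TGFβ in many cells, was high in mTO-iTreg cells although no TGFβ was listed: 564 ± 27.7 against 62.9 ± 18.5 in TGFβ-iTreg cells. It went against the TGFβ response list, where more called members were lower than higher and which did not pass (camera adjusted p = 0.096). Ebi3, Tnfrsf9 and Eomes were higher than in TGFβ-iTreg cells too, and Maf and Itgae were lower.

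Cdkn1a and Psrc1 are targets of the DNA damage factor p53, so p53 activity may be higher in mTO-iTreg cells. Of 27 other p53 targets with enough signal, 15 were higher than in TGFβ-iTreg cells and 1, Sesn1, lower. The median log2 change was 1.01 (bootstrap interval 0.10 to 1.69), with camera p = 0.00053, and 0.0497 with an estimated correlation. This list was tested alone and these p-values are unadjusted. They cannot be set beside the adjusted values of the lists fixed in advance. Against day 0 the medians were 1.20 in mTO-iTreg and 0.33 in TGFβ-iTreg cells (0.16 with genes at 0 set to their bound). Plk2 rose from 17.0 ± 2.97 to 181 ± 57.5 between the iTreg groups, Ccng1 from 556 ± 107 to 1731 ± 506, and Mdm2, which p53 induces and which restrains it, changed by 0.82 log2. Of the 27 targets, 20 changed upward between the iTreg groups. Pmaip1 (-1.04 log2) and Bbc3 (-0.39) changed downward without passing. From day 0, Bbc3 and Rps27l rose more in TGFβ-iTreg (1.45 and 1.68 log2) than in mTO-iTreg cells (1.06 and 1.43). The list's median thus moved the way the hypothesis needs, though not every member did. The IL-2 dose, the organoids and whatever the other form of library code stands for cannot be separated, and other pathways also raise Cdkn1a.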
